A study of Homo sapiens with 4 samples.

How the data were processed

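Total RNA of Raji cells, grown per the labels in RPMI medium with 10% serum at 37 °C and 5% CO2, was sequenced as 4 libraries. The values analysed are the authors' deposited raw counts of reads per gene, whole numbers that had not been normalised, for 58037 genes, and the libraries were not pooled. Per the submitters' processing notes, BWA, featureCounts and Subread 1.4.6-p3 were used with genome build GRCh38. The deposited count table is named for GENCODE release 25. The strand, multi-mapping and overlap settings of the counting are not given in the sources used here. Without them, reads of near-identical copies, of overlapping genes and of antisense genes cannot be assigned with certainty. The role of BWA is not given either. By itself BWA does not split reads across introns. If it aligned the reads, those over exon junctions can be lost or placed on processed pseudogenes, so such genes are uncertain here. Columns of the table carry the numbers 1 to 4 of the Raji wild type and were matched to the replicates by number, and 0 columns were left unused.

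Per the labels' protocols, replicates 1 and 2 were prepared with the ScriptSeq kit and replicates 3 and 4 with a small RNA kit under a modified protocol, whose details are not given in the sources used here. The original plan described the splits of the replicates as unlabelled. That was an oversight, since the labels did name the kits, and the kit was recognised only after the counts had been seen. The split of replicates 1 and 2 against 3 and 4 is therefore reported as a comparison of library kits, a technical batch, and within-kit values were added. The gene lists, gene pairs, list pairs, tests, thresholds and most alternatives were chosen before the data were examined; the within-kit values, division by exon length, the kit factor, the ranks within each kit, the bounds from single libraries, the protein-coding subset, total-count scaling of the split and offsets for gene properties were chosen after seeing the data.

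Gene names, classes and coordinates came from GENCODE release 29 (GRCh38), since release 25 was not used here. Of 58037 identifiers, 57433 matched without their version, and the 604 unmatched genes held at most 0.026% of a library's counts. Because that release is not the one counted, levels were not divided by gene length in the main analysis: the level is log2 of CPM plus 0.1, scaled by TMM factors of 1.43, 1.47, 0.706 and 0.672 for replicates 1 to 4. Depth was 40613875, 39230833, 51733181 and 69459408 counts, with 27264, 27908, 23958 and 25244 genes detected. The floor was 3 counts per library, and shares carry exact binomial 95% intervals.

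Tests between splits of the replicates used the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on genes kept by filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjustment at 0.05; DESeq2 1.42.0 served as an alternative. Replicate pairs were compared by chi-square tests of their counts, and single genes by a chi-square dispersion test over genes with a mean count of at least 20. For 38 gene lists, the median level was set against 10000 random lists of the same size, two-sided. These were drawn from all genes of the members' classes pooled, without keeping the share of each class. The range of the members' deviations between libraries was set against 10000 lists matched on mean expression in 20 bins. For 12 list pairs, the difference was that of the mean levels of their members, and genes were permuted 100000 times. In 26 gene pairs the log2 ratio was given per library, with two-sided exact sign-flip tests. In the lists, 2 symbols were left out, RMRP, since 2 identifiers share the name, and RNY5, since no identifier matched it; the RMRP named among the folds is the only one of its 2 identifiers with counts. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

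The genes named are those of a fixed rule: the 25 with the highest mean CPM; in each list the 3 highest members and the lowest; the members of gene pairs; the 10 with the largest dispersion among genes with a mean count of at least 50; the 3 most deviating members of each list called for spread; and the 5 largest folds in each direction of a split that calls genes. Dispersion was ranked only over genes that the filter kept, which needed counts in all 4 libraries. Genes named because they had a count of 0 under overlapping annotation, and V genes, copy families and pseudogenes in the closing part, were chosen after their values were seen. Results of some genes that the rule takes are not reported here. No biological contrast exists in a design of 1 group, and none was tested.

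The scripts were tested on simulated data. For the split of 2 and 2 libraries, all counts were simulated from the real means and from dispersions with the kit as a factor. Of 200 changed genes, those that passed the filter were tested. Among them edgeR called 23.7% of 93 2-fold and 71.6% of 95 4-fold changes, with 20 false calls among 17564 genes. As a share of all edgeR calls in this simulation, the false calls exceeded the Benjamini-Hochberg threshold. The dispersion test recovered 89% of 200 varying genes, with 9 false calls among 15581. Alternatives covered the scaling (DESeq2 size factors, upper quartile, total counts), filters, pseudocount, expression floor, background of the lists, summary by mean, and each replicate left out in turn.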

Results

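Raji is an established B cell line from a Burkitt lymphoma, a tumour of germinal centre B cells in which MYC is joined to an immunoglobulin locus, and it carries Epstein-Barr virus. Total RNA of these cells was sequenced as 4 libraries of 1 group, with no treatment and no second group. The questions addressed here are which genes the cells expressed, at what level, and how far the libraries differed. The submitters call the samples biological replicates but do not say that they came from separate cultures, so p-values between them measure only the spread between these samples, which may be technical. Per the labels, replicates 1 and 2 were prepared with the ScriptSeq kit for total RNA, and replicates 3 and 4 with a kit for small RNA under a modified protocol. The kit is therefore a technical batch with 2 libraries on each side, and means over the 4 libraries mix both kits. Genes whose kit means lay over 3-fold apart, and lists whose kit medians lay over 1 apart on the log2 scale, are given for each kit too, in the order ScriptSeq and small RNA kit used throughout. Total counts were 40613875 in replicate 1, 39230833 in replicate 2, 51733181 in replicate 3 and 69459408 in replicate 4. A count of 0 allowed up to 0.0517, 0.0519, 0.0821 and 0.0643 TMM-normalised CPM in replicates 1 to 4. Intervals and floors cover counting error only.

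Nuclear protein-coding transcripts took 68.9% and 68.7% of the counts in replicates 1 and 2, and 37.9% and 36.0% in replicates 3 and 4. Small nucleolar RNAs, which guide the processing and modification of ribosomal RNA, took 0.305% and 0.135% with ScriptSeq against 21.9% and 18.0% with the small RNA kit. Small nuclear RNAs, the RNA parts of the spliceosome, took 3.06% and 3.09% against 17.5% and 16.2%. Mitochondrial ribosomal RNA went the other way. It took 16.7% and 15.8% of counts with ScriptSeq. With the small RNA kit, replicate 3 had 0.0116% (exact binomial 95% interval 0.0113% to 0.0119%) and replicate 4 had 0.0385% (0.0381% to 0.0390%). Mitochondrial transfer RNAs took 0.0212% and 0.0227% against 3.00% and 2.67%, and mitochondrial messenger RNAs 2.57% and 2.45% against 0.0497% and 0.0710%. Miscellaneous RNAs, among them 7SL and Y RNAs, differed within a kit as well, at 0.753% and 1.90% with ScriptSeq and 8.64% and 16.2% with the small RNA kit. Processed pseudogenes held 5.47% ± 0.452 (SD, n = 4) and long non-coding RNAs 1.54% ± 0.297 of the counts. Immunoglobulin genes held 0.0439% ± 0.0162, with kit means of 0.0579% and 0.0299%. The 100 most counted genes took 34.1% of the counts in replicates 1 and 2, and 59.7% and 61.1% in replicates 3 and 4.

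**Figure D1:**
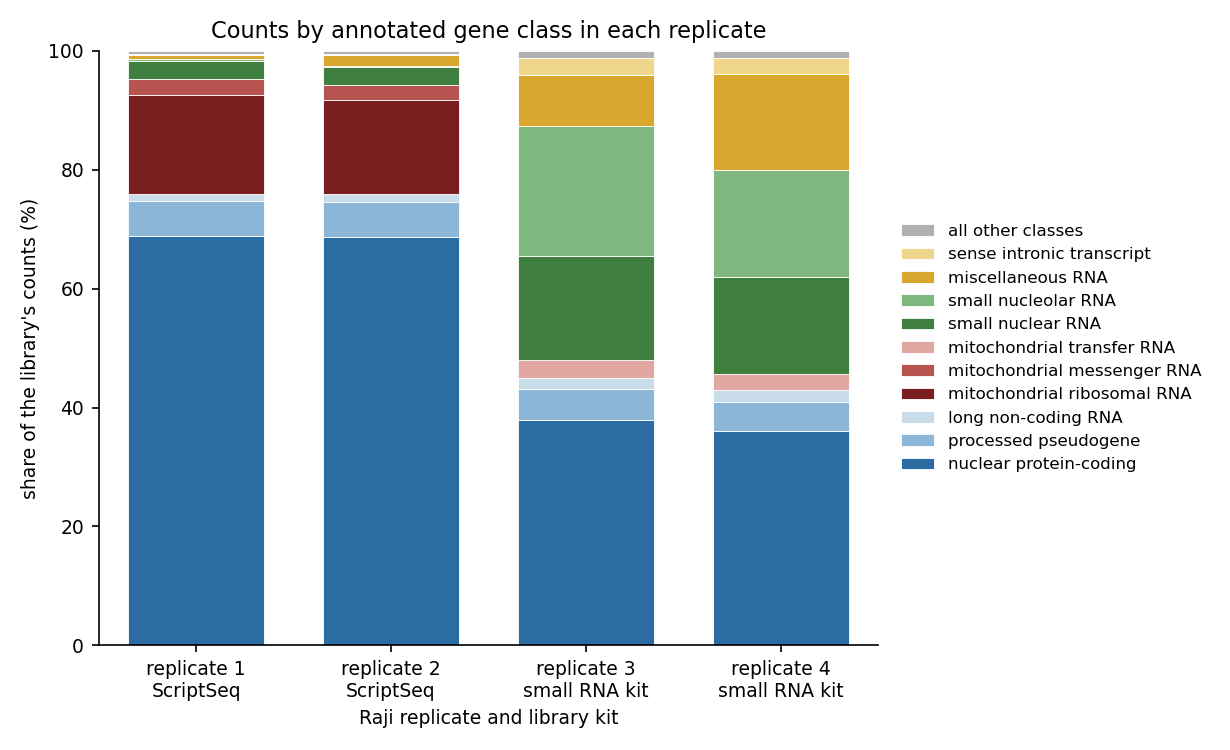
Share of counts (%) by annotated gene class in each of the 4 Raji libraries, replicates 1 and 2 made with ScriptSeq and replicates 3 and 4 with the small RNA kit. Nuclear protein-coding genes hold 68.9% in replicate 1 and 36.0% in replicate 4, and small nucleolar RNAs 0.305% and 18.0%.

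The order of abundance differed between the kits. With ScriptSeq, the mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 were highest at 85846 and 26037 CPM, then RNU2-6P, a copy of the U2 small nuclear RNA, at 13662 CPM and EEF1A1P5 at 5518 CPM. Genes annotated as nuclear protein-coding made up 10 of the 25 highest there and 2 of the 25 highest with the small RNA kit, where 10 were small nuclear RNAs and 3 small nucleolar RNAs. Those with ScriptSeq included MTRNR2L12, named as MT-RNR2-like, with 139530, 135399, 40 and 196 counts in replicates 1 to 4. The source of its reads is uncertain. Averaged over both kits, small structured RNAs led, and of the 25 highest by that mean 9 were also among the 25 highest with ScriptSeq and 22 with the small RNA kit. SNORD3A (ENSG00000263934.4, GRCh38 chromosome 17, 19188016 to 19188714, plus strand), the U3 small nucleolar RNA, averaged 67359.7 CPM, from 794 CPM over replicates 1 and 2 to 133925 CPM over replicates 3 and 4. RN7SL2 (ENSG00000274012.1, chromosome 14, 49862550 to 49862849, minus strand), a 7SL RNA of the signal recognition particle, averaged 46989.8 CPM, from 1398 to 92582 CPM. SNORD3C, a near-identical copy of SNORD3A, held 0.422 and 93566 CPM in the kits. In replicates 3 and 4, SNORD3A had 201459 and 66391 CPM and SNORD3C 46518 and 140615 CPM, so values of single copies are uncertain. With the small RNA kit, MT-RNR2 and MT-RNR1 had 328 and 41.4 CPM. RN7SL5P, RN7SL4P, RNU5A-1, RNU5B-1, RNU5E-1, RNVU1-7, RNU2-6P, 1 copy of U1 and 3 of U2 (listed as RF00003 and RF00004), SNORD104, the 5S ribosomal RNA RNA5S7, the mitochondrial transfer RNAs MT-TE and MT-TS2, and AC051619.8, an intronic transcript on chromosome 15, were also among the 25 highest by the mean over both kits. The remaining 4 included EEF1A1, the translation elongation factor, at 7641 ± 5506 CPM (SD, n = 4) with 2950 and 12332 CPM in the kits, and its processed pseudogene EEF1A1P5 at 10487 ± 5782 CPM. The others were the long non-coding RNA GAS5, a snoRNA host gene, at 5950.5 ± 6701 CPM with 175 and 11726 CPM in the kits, and HSPA8, a constitutive chaperone, at 4629 ± 1791 CPM. In all, 11194 genes reached 1 CPM in every library, of which 9305 were nuclear protein-coding genes, 999 processed pseudogenes and 436 long non-coding RNAs. Replicates 1 and 2 alone gave 12237 genes and replicates 3 and 4 alone 12550.

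B cell transcripts were abundant in every library. CD74, the invariant chain of MHC class II (chromosome 5, 150401637 to 150412929), averaged 656 ± 280.5 CPM (SD, n = 4), MS4A1, which encodes CD20, 341 ± 128 CPM, and CD79B, a signalling chain of the B cell receptor, 259 ± 155 CPM with 124 and 393 CPM in the kits. All 20 members of the B cell identity list were expressed, the lowest being VPREB3 at 6.76 ± 1.35 CPM. The median level of the list, on a log2 scale of CPM with 0.1 added, was 5.24 ± 0.47 (SD over the 4 libraries' medians), against −0.20 for random lists of the same size (permutation test, adjusted p = 0.000585). Within kits it was 5.59 and 4.78. For every list, the median given is that of the members' mean levels over the 4 libraries. The SD is that of the single libraries' medians, which can all lie above or all below the value given. The 15 genes of B cell receptor signalling had a median of 6.23 ± 0.33 (permutation, adjusted p = 0.000585). PIK3AP1 led at 248 ± 25.8 CPM, PRKCB at 176 ± 30.8 CPM and PLCG2 at 168 ± 45.5 CPM, with BCL10 lowest at 10.4 ± 0.672 CPM. The germinal centre and Burkitt programme stood at 5.56 ± 0.29 (permutation, adjusted p = 0.00095). In it STMN1, a microtubule regulator, was at 403 ± 193 CPM, RGS13 at 148 ± 26.6 CPM and MME, the CD10 antigen, at 99.9 ± 14.4 CPM, while MEF2B was lowest at 0.734 ± 0.512 CPM with 1.16 and 0.313 CPM in the kits. MYC itself (ENSG00000136997.15, chromosome 8, 127735434 to 127741434, plus strand) averaged 69.8 ± 39.4 CPM, with 98.9 and 108 CPM in replicates 1 and 2 and 35.0 and 36.8 CPM in replicates 3 and 4.

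IGHM, the constant region of the mu heavy chain (chromosome 14, 105851705 to 105856218, minus strand), averaged 304 ± 8.01 CPM (SD, n = 4). IGLC2, a lambda constant region, averaged 18.3 ± 3.27 CPM, IGLL5 29.4 ± 19.8 CPM with 12.3 and 46.5 CPM in the kits, and IGKC, the kappa constant region, 6.71 ± 0.390 CPM. IGLC1 had a count of 0 in all 4 libraries, and every base of its exons overlaps another gene on the same strand. The 16 genes of the immunoglobulin constant region list together did not stand apart, at a median of 1.34 ± 0.41 (permutation, adjusted p = 0.699). Its random lists came from constant region and protein-coding genes pooled, of which protein-coding genes are by far the more numerous. Plasma cell genes had a median of 4.08 ± 0.32, which missed the threshold (permutation, adjusted p = 0.0690) but passed with the mean of the members' levels in place of the median (0.00624). They included HSP90B1 at 514 ± 126 CPM, JCHAIN at 412 ± 262 CPM (186 and 638 CPM in the kits) and SEC11C at 86.6 ± 27.6 CPM, and no count of ELL2. Host targets of NF-kB and of the viral growth programme stood at 3.73 ± 0.15 (permutation, adjusted p = 0.109), or 3.99 to 4.36 in single libraries. BIRC3 led at 508 ± 20.6 CPM, then CD83 at 67.8 ± 2.19 CPM and NFKB2 at 52.0 ± 7.18 CPM, with TNFAIP2 at 0. In replicates 1 and 2 alone the list passed, at 4.26 (permutation, adjusted p = 0.0408), and without replicate 3 at 4.36 (0.0463). It passed as well with the mean of its members (permutation, adjusted p = 0.00117) and per kb of exon (0.00296).

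Antigen presentation genes were expressed throughout, with all 14 members of each MHC list at 1 CPM or more in every library. The class II list had a median of 5.71 ± 0.25 (permutation, adjusted p = 0.00095), with HLA-DRA at 503 ± 223 CPM and HLA-DPA1 at 167 ± 80.5 CPM, down to the thiol reductase IFI30 at 7.34 ± 4.34 CPM with 3.59 and 11.1 CPM in the kits. For class I the median was 5.45 ± 0.28 (permutation, adjusted p = 0.00179). B2M, the light chain, was at 776 ± 315 CPM and HLA-B at 284 ± 132 CPM, and the immunoproteasome subunit PSMB10 lowest at 16.2 ± 13.4 CPM with 4.61 and 27.9 CPM in the kits. Interferon-stimulated genes did not stand apart, at −0.90 ± 0.23 (permutation, adjusted p = 0.864). Its members included STAT2 at 17.4 ± 3.34 CPM, OAS2 at 14.5 ± 1.34 CPM and no count of RSAD2. Toll-like receptors and adaptors stood at 3.28 ± 0.08 (permutation, adjusted p = 0.249), or 3.02 to 3.21 in single libraries. They included IRAK1 at 163 ± 52.6 CPM, TLR10 at 62.8 ± 4.06 CPM, CD180 at 44.6 ± 22.3 CPM and TLR8 at 0.

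Lists of markers of other lineages had medians near or at the floor, though single members were counted in every library. The erythroid and platelet list and the fibroblast and endothelial list each had a median at the floor of −3.32 (permutation, adjusted p = 0.0308), as did the neuronal list (permutation, adjusted p = 0.0445), which placed them below random lists. These 3 calls were lost without replicate 1, with adjusted p of 0.0619, 0.0619 and 0.0725, and without replicate 2, with 0.0593, 0.0593 and 0.0785. The neuronal call was lost also without replicate 3 (0.0535) or replicate 4 (0.0608), and in each kit alone none of the 3 passed (permutation, adjusted p from 0.0641 to 0.167). Their highest members were EPOR at 3.04 ± 1.15 CPM, COL1A1 at 2.46 ± 1.14 CPM and MAP2 at 1.498 ± 0.770 CPM (SD, n = 4). T and NK cell markers had a median of −3.21 ± 0.16 (permutation, adjusted p = 0.0867), with only the kinase LCK above 1 CPM in every library, at 8.21 ± 6.05 CPM with 2.99 and 13.4 CPM in the kits. Myeloid markers stood at −3.23 (permutation, adjusted p = 0.0787), led by ITGAM at 3.29 ± 0.759 CPM, and epithelial markers at −3.29 (permutation, adjusted p = 0.0560), led by CLDN4 at 0.0873 ± 0.0336 CPM. HOX genes had a median of −3.19 ± 0.26 (permutation, adjusted p = 0.150), with HOXB4 at 2.91 ± 1.22 CPM and HOXB7 at 2.18 ± 0.376 CPM. Germline and cancer-testis genes had a median at the floor of −3.32 (permutation, adjusted p = 0.0648), with PRAME highest at 2.20 ± 0.217 CPM, then DDX4 at 0.0858 ± 0.0367 CPM. With the mean of the members' levels in place of the median, the last 5 lists also lay below random lists, with adjusted p (permutation) of 0.000661 for the T and NK, myeloid and epithelial lists, 0.0203 for HOX genes and 0.000422 for germline genes.

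The cells carried high levels of cell cycle and growth transcripts. TOP2A, the mitotic topoisomerase, averaged 521 ± 21.7 CPM (SD, n = 4), MCM3, a replicative helicase subunit, 346 ± 37.1 CPM, and MKI67, the proliferation marker Ki-67, 695 ± 661 CPM, with 1267 CPM over replicates 1 and 2 and 123 CPM over replicates 3 and 4. The proliferation list had a median of 6.78 ± 0.34 (permutation, adjusted p = 0.000585), and its lowest member was CCNE1 at 9.29 ± 1.04 CPM. MYC-target ribosome biogenesis genes stood at 6.94 ± 0.09 (permutation, adjusted p = 0.000585). They were led by nucleolin (NCL) at 976 ± 384 CPM, nucleophosmin (NPM1) at 774 ± 329.5 CPM and GNL3 at 195 ± 23.9 CPM, and RRP9 lowest at 35.0 ± 25.4 CPM with 13.2 and 56.9 CPM in the kits. CDK inhibitors and quiescence genes had a median of 3.73 ± 0.34 (permutation, adjusted p = 0.113), led by RB1, RBL2 and BTG2 at 66.6 ± 23.9, 63.3 ± 17.3 and 53.4 ± 18.8 CPM, with KLF2 at 0. The p53 targets stood at 3.93 ± 0.51 (permutation, adjusted p = 0.0848), with MDM2 at 176 ± 32.2 CPM, RRM2B at 126 ± 32.9 CPM and FAS at 55.7 ± 6.82 CPM. With the mean of the members' levels both lists passed (permutation, adjusted p = 0.0287 for CDK inhibitors and 0.00591 for p53 targets), and per kb of exon the p53 targets did (0.0491). Anti-apoptotic BCL2 genes had a median of 4.05 ± 0.14 (permutation, adjusted p = 0.204) and pro-apoptotic ones of 2.82 ± 1.07 (permutation, adjusted p = 0.442), with 2.27 and 4.10 in the kits. MCL1 averaged 130.3 ± 31.0 CPM, BCL2 30.6 ± 3.66 CPM and BCL2L1 20.6 ± 1.28 CPM. On the other side, BCL2L11 (BIM) was at 63.8 ± 41.9 CPM with 100.1 and 27.5 CPM in the kits, PMAIP1 (NOXA) at 63.6 ± 39.01 CPM with 30.03 and 97.2 CPM, and BID at 41.1 ± 28.0 CPM with 17.2 and 65.1 CPM. BCL2L10 and BOK had no count.

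Energy metabolism and translation gave some of the highest list medians. Cytosolic ribosomal protein and elongation factor genes stood at 9.08 ± 0.71, glycolysis at 7.29 ± 0.38 and nuclear-encoded oxidative phosphorylation at 6.72 ± 0.74 (permutation, adjusted p = 0.000585 for each). In the kits the first had 8.39 and 9.61 and the last 6.12 and 7.40. RPS6 averaged 2163 ± 1246 CPM and EEF2 1140.0 ± 420.5 CPM (SD, n = 4), and RPLP1 was the lowest of its list at 179 ± 114 CPM with 277 and 80.8 CPM in the kits. Among glycolytic genes ENO1 reached 2625 ± 1415 CPM, GAPDH 1356 ± 654 CPM and LDHB 1129.9 ± 155 CPM, with the glucose transporter SLC2A1 lowest at 31.7 ± 6.01 CPM. ATP5A1 and ATP5B, subunits of ATP synthase, averaged 673 ± 342 and 511 ± 160 CPM, cytochrome c (CYCS) 398 ± 26.9 CPM and SDHC 4.37 ± 1.55 CPM. The 13 mitochondrially encoded messenger RNAs stood at 7.54 ± 2.74 (permutation, adjusted p = 0.000585), with 10.01 over replicates 1 and 2 and 5.29 over replicates 3 and 4. MT-CO1 held 5018 and 379 CPM in the kits, MT-ND4 3207 and 86.8 CPM, MT-CO2 1723 and 88.1 CPM, and MT-ATP8 264 and 5.61 CPM.

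Of transcription and chromatin genes, the polymerase II and elongation lists passed. Pausing, elongation and termination factors had a median of 5.27 ± 0.04 (permutation, adjusted p = 0.000585), or 5.40 to 5.48 in single libraries. In this list were SUPT16H and SSRP1, the FACT histone chaperone, at 656 ± 60.3 and 283 ± 9.80 CPM, the nuclease XRN2 at 118 ± 16.3 CPM and NELFA at 7.11 ± 0.619 CPM. RNA polymerase II subunits stood at 5.16 ± 0.44 (permutation, adjusted p = 0.00844), led by POLR2B at 300.2 ± 21.4 CPM, POLR2E at 80.8 ± 43.8 CPM and POLR2K at 65.2 ± 15.2 CPM. DNA methylation and Polycomb genes stood at 3.67 ± 0.35, which did not pass by the median (permutation, adjusted p = 0.132) but did by the mean of the members' levels (0.0115). The maintenance methyltransferase DNMT1 averaged 323 ± 215 CPM with 508 and 137 CPM in the kits, SUZ12 90.5 ± 25.4 CPM and EZH2 89.2 ± 17.1 CPM. Unfolded protein response genes stood at 5.60 ± 0.12 (permutation, adjusted p = 0.00095). Calreticulin (CALR) was at 1194 ± 354 CPM, calnexin (CANX) at 860.1 ± 121 CPM and PDIA6 at 391 ± 187 CPM. Immediate early and stress genes did not stand apart, at 0.23 ± 0.13 (permutation, adjusted p = 0.903), or 0.66 to 0.92 in single libraries. They included HSPH1 at 532 ± 34.3 CPM and the near-identical pair HSPA1A and HSPA1B at 212 ± 87.1 and 66.1 ± 25.4 CPM. Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, stood at 6.45 ± 1.35 (permutation, adjusted p = 0.000585), with 5.21 and 7.53 in the kits. HIST1H2AG held 67.4 and 1097 CPM, HIST1H3H 28.8 and 894 CPM and HIST1H1B 255 and 609 CPM. HIST1H3D had no count, and its exons lie wholly within another gene's exons on the same strand. Replication-independent histones stood at 4.33 ± 0.08 (permutation, adjusted p = 0.0915), or 4.41 to 4.61 in single libraries. They were led by H2AFZ, H3F3B and H2AFY at 338 ± 178, 150.3 ± 44.6 and 131 ± 66.4 CPM. They passed per kb of exon (permutation, adjusted p = 0.0201) and against expressed genes alone (0.0395).

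Nuclear and host-gene long non-coding RNAs had a median of 5.75 ± 0.14 (permutation, adjusted p = 0.000585), led by GAS5, the snoRNA host SNHG1 at 2354 ± 2668 CPM (63.2 and 4644 CPM in the kits) and the nuclear speckle RNA MALAT1 at 1511 ± 1153 CPM (2507 and 515 CPM), with H19 at 0. RNAs made by RNA polymerase III stood at 3.67 ± 4.26 and the small nuclear and nucleolar RNAs made by RNA polymerase II at 4.72 ± 4.48 (permutation, adjusted p = 0.000585 for each), with kit medians of −0.80 and 6.56 for the first and 0.31 and 8.07 for the second. RNY4 and RNY1, Y RNAs bound by the Ro protein, held 2.98 and 3.18 CPM with ScriptSeq and 4550 and 1981 CPM with the small RNA kit. RPPH1, RN7SK and RN7SL1 of the first list and SCARNA2, RNU12 and SNORD118 of the second had no count in any library. None of them has an exon base free of a neighbour on the same strand. Their counts of 0 enter the medians of both lists but may say nothing about expression. Of the 38 lists, 21 were called, 18 above and 3 below random lists, and 0.0002 was the smallest p that 10000 random lists can give. By the mean of the members' levels 31 lists were called, 23 above and 8 below, and per kb of exon 24, with all 21 of the calls kept in both. In each kit alone 19 and 18 were called, 18 of the 21 in each, without the 3 below. Set against expressed genes alone, 30 lists could be tested and 13 were called, 12 of the 21 and the replication-independent histones. The 3 lists below were not among those tested, and the calls were lost for B cell identity (adjusted p = 0.174), MHC class II (0.0681) and class I (0.146), polymerase III RNAs (0.4001), polymerase II subunits (0.217) and pausing factors (0.136). These p-values are permutations over genes, which are not independent replicates, and describe these libraries.

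**Figure D2:**
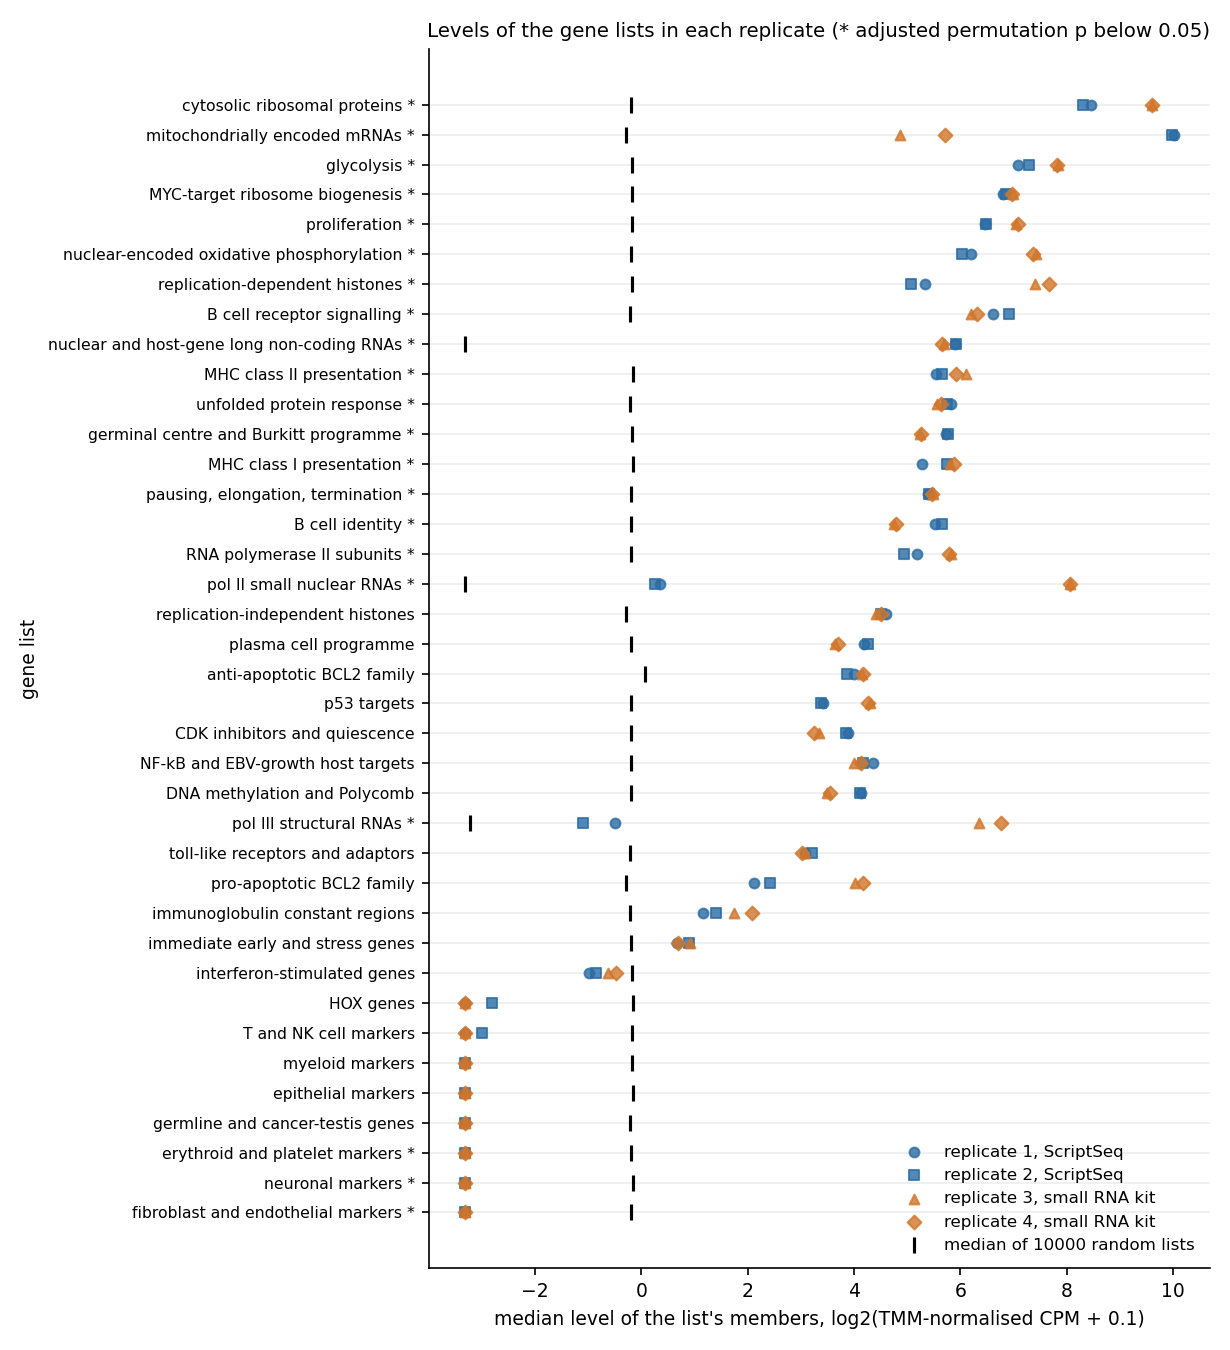
Median level of each of the 38 gene lists in each Raji library, as log2 of CPM with 0.1 added, 1 symbol per replicate. The ribosomal protein list is at 9.08 over the replicates, the erythroid and platelet, fibroblast and endothelial, and neuronal lists lie at the floor of −3.32, and mitochondrially encoded messenger RNAs part from 10.01 with ScriptSeq to 5.29 with the small RNA kit.

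List pairs were compared by the mean of the members' levels, so the differences are not those between the medians given above. B cell identity genes exceeded T and NK cell markers by 8.19 ± 0.24 and myeloid markers by 8.12 ± 0.13 on the log2 scale (SD over 4 libraries), higher in 4 of 4 libraries (permutation over genes, adjusted p = 4.0e-05 for each). Proliferation genes exceeded CDK inhibitors and quiescence genes by 3.76 ± 0.26 (permutation, adjusted p = 4.0e-05), and MYC-target ribosome biogenesis genes exceeded p53 targets by 3.45 ± 0.01 (permutation, adjusted p = 6.0e-05), both in 4 of 4 libraries. Glycolysis lay 1.35 ± 0.08 above oxidative phosphorylation in 4 of 4 libraries without passing the correction over 12 pairs (permutation, adjusted p = 0.0724). The germinal centre programme lay 1.59 ± 0.03 above the plasma cell programme (permutation, adjusted p = 0.194) and 1.21 ± 0.08 above NF-kB targets (permutation, adjusted p = 0.210), each in 4 of 4 libraries. MHC class II and class I differed by 0.13 ± 0.21 (permutation, adjusted p = 0.852), and anti-apoptotic and pro-apoptotic genes by 0.39 ± 0.56 (permutation, adjusted p = 0.852), with the sign of these means following the kit in both, whereas by kit medians the first list of each pair was the higher in both kits. Replication-dependent histones lay 2.82 ± 1.20 above replication-independent ones (permutation, adjusted p = 0.0847), and passed in replicates 3 and 4 alone at 3.85 (adjusted p = 0.0197). The mitochondrially encoded messenger RNAs lay 0.95 ± 3.01 above nuclear-encoded oxidative phosphorylation (permutation, adjusted p = 0.194). The kits had opposite signs, with 3.55 in replicates 1 and 2 alone (adjusted p = 4.0e-05) and −1.65 in replicates 3 and 4 alone (adjusted p = 0.0240). Without replicate 3 or replicate 4 the difference was 1.91 (adjusted p = 0.00614) or 1.72 (0.0146). RNAs of polymerase III and of polymerase II differed by −0.77 ± 0.40 (permutation, adjusted p = 0.845). Both means include members at a count of 0 whose exons lie under another gene on the same strand, so this difference is uncertain. The exact sign-flip test over 4 libraries cannot go below 0.125 and so could not pass the threshold for any pair.

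In 24 of the 26 gene pairs the log2 ratio had the same sign in all 4 libraries, where the two-sided exact sign-flip test gives its smallest possible p of 0.125. IGHM exceeded IGHG1 by 3.89 ± 0.45 (log2, SD, n = 4) and IGHD by 7.03 ± 1.23, and IGKC lay below IGLC2, at −1.42 ± 0.18. BCL6, the germinal centre repressor, exceeded PRDM1, the plasma cell regulator, by 6.07 ± 0.26, or by 5.02 with 1 CPM added in place of 0.1 CPM, IRF8 exceeded IRF4 by 2.03 ± 0.64, and MS4A1 exceeded CD38 by 3.69 ± 0.34. MYC exceeded MAX, its binding partner, by 1.43 ± 0.36. MYCN had no count in any library, CD3E at most 2 counts and PKLR at most 1. The ratios of MYC over MYCN, 9.25 ± 0.88, of CD79A over CD3E, 8.69 ± 0.05, and of PKM over PKLR, 13.17 ± 0.63, are therefore set by the added 0.1 CPM, and with 1 CPM added they were 5.96, 5.54 and 9.95. CCND3 exceeded CCND2 by 7.27 ± 0.32 and CCND1 by 7.98 ± 0.39, or by 5.15 and 5.28 with 1 CPM added. DNMT1 exceeded DNMT3A by 8.85 ± 0.69, or by 7.46 with 1 CPM added, EZH2 exceeded EZH1 by 2.32 ± 0.67, and H2AFZ exceeded H2AFX by 2.82 ± 0.31. MCL1 exceeded BCL2 by 2.06 ± 0.52, and BCL2 exceeded BCL2L1 by 0.56 ± 0.11, which reversed to −1.23 per kb of exon. LDHA lay below LDHB at −0.47 ± 0.05, and MALAT1 exceeded NEAT1 by 3.22 ± 0.16. Per kb of exon MCL1 over BCL2 came to 3.45, LDHA over LDHB to −1.52 and MALAT1 over NEAT1 to 4.55, since ratios of genes of unequal length shift with that division. Several pairs moved with the kit, with 5.81 and 1.69 for TCF3 over ID3, 0.63 and 3.02 for CD40 over TNFRSF13C, −4.29 and −0.13 for BAX over BCL2L11, and −0.12 and −1.74 for POLR2A over POLR1A. No sign held in HK2 over HK1, at 0.32 ± 0.41 (exact p = 0.375), or in POLR2A over POLR3A, at −0.15 ± 1.03 (exact p = 0.750).

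**Figure D3:**
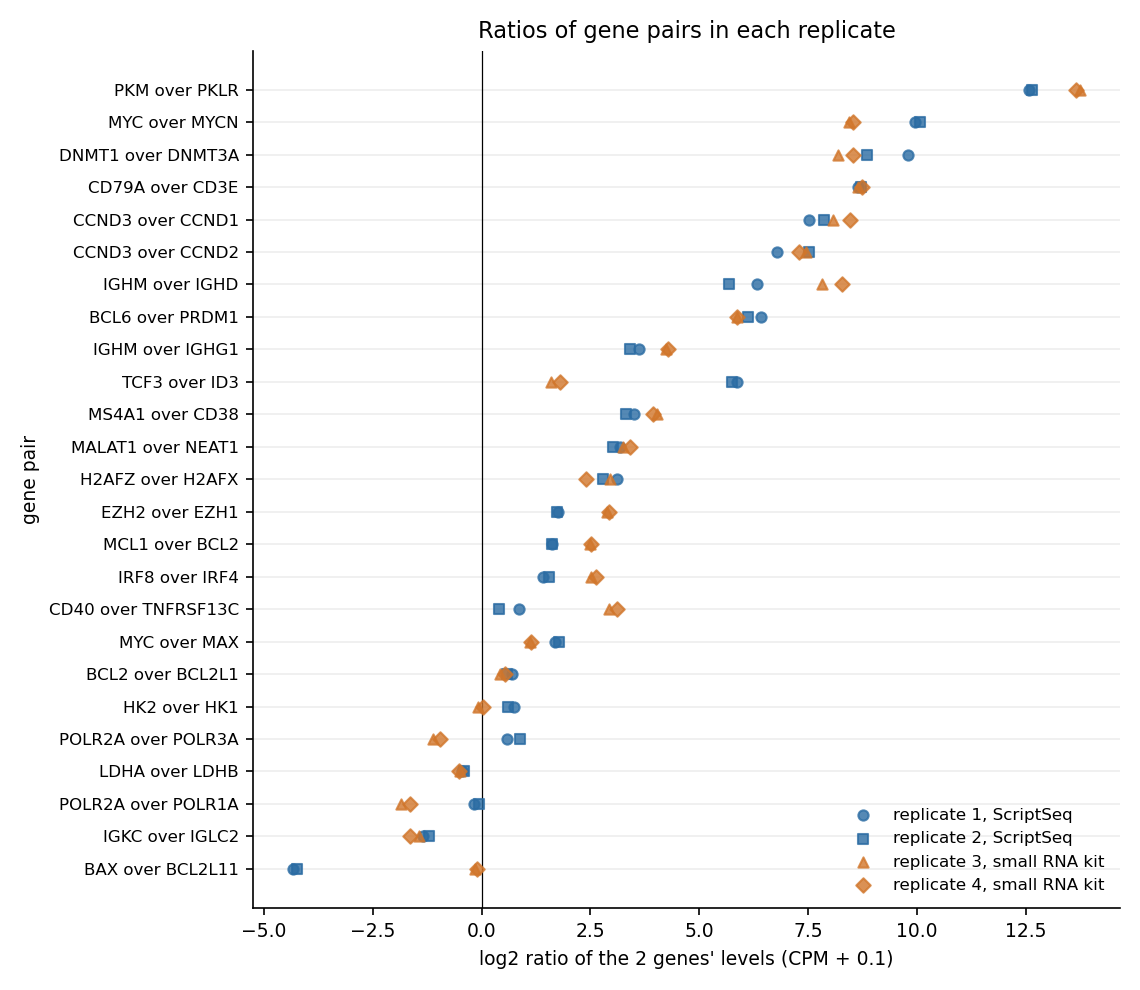
Log2 ratio of the 2 genes of 25 of the 26 pairs in each Raji library, 1 symbol per replicate, with 0.1 CPM added to both genes. PKM over PKLR is highest at 13.17 on average, which the added 0.1 CPM sets since PKLR had at most 1 count (9.95 with 1 CPM added), and TCF3 over ID3 separates into 5.81 with ScriptSeq and 1.69 with the small RNA kit.

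Between the kits, the clearest differences lay in short and in mitochondrial RNAs. RMRP, the RNA of RNase MRP (ENSG00000269900.3), had no count in replicates 1 and 2 and 1831 CPM in replicates 3 and 4. A second identifier of that name lies within the same bases on the same strand and had no count in any library, so a count of 0 is uncertain for this gene and no fold is given. Other genes at 0 were set against a floor of 3 counts per library. A copy of the U8 small nucleolar RNA listed as RF00096 was at least 9606-fold higher. SNORD118, also U8, had no count in any library and no exon base free of a neighbour on the same strand. How U8 reads were assigned is therefore unknown, and the bound of this copy is uncertain. The long non-coding RNA AC004232.2 was at least 5136-fold higher, or 3205-fold without replicate 3. SNORD3C was 17.75 ± 1.25 (SE) higher on the log2 scale (edgeR, adjusted p = 0.000387) and RNU5A-1, a spliceosomal U5 RNA, 12.79 ± 0.99 higher (edgeR, adjusted p = 0.000499). With each replicate left out the folds ranged from 16.74 (without replicate 4) to 18.63 (without replicate 1) and from 12.16 (without replicate 2) to 13.92 (without replicate 1). SNORD3A, the near-identical copy, was 7.40 ± 1.14 higher (edgeR, adjusted p = 0.0043), or 6.38 (without replicate 3) to 8.83 (without replicate 1). The U5 copies together went from 35.4 and 9.25 CPM in replicates 1 and 2 to 89834 and 73455 CPM in replicates 3 and 4. In the other direction, MT-RNR2 was at −8.03 ± 0.84 (edgeR, adjusted p = 0.00126) and the U2 copy RNU2-6P at −6.79 ± 0.51 (edgeR, adjusted p = 0.000472), which ranged from −9.24 (without replicate 4) to −7.39 (without replicate 3) and from −7.41 (without replicate 3) to −6.35 (without replicate 4). The copies of U2 together went the opposite way, from 17596 and 15467 CPM in replicates 1 and 2 to 79260 and 79503 CPM in replicates 3 and 4. The mitochondrial pseudogene MTCO1P25 and the U6 copies RNU6-1323P, RNU6-1301P, RNU6-74P and RNU6-936P had no count in replicates 3 and 4, and were at least 270-, 274-, 198-, 156- and 99.2-fold lower there. Replicate 2 carries the bounds of the U6 copies, which without it were 83.5-, 86.8-, 18.4- and 9.65-fold. The calls of RNU6-74P and RNU6-936P were lost without replicate 3 (adjusted p = 0.0937 and 0.108) or replicate 4 (0.104 and 0.119). By class, 216 of 232 tested small nucleolar RNAs were higher with the small RNA kit and 7 lower, 19 of 22 mitochondrial transfer RNAs were higher and 0 lower, and all 13 mitochondrial messenger RNAs and both mitochondrial ribosomal RNAs were lower. Of long non-coding RNAs, 207 of 2027 were higher and 791 lower, and of protein-coding genes 3467 of 10835 were higher and 3379 lower.

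Over all classes, edgeR called 11370 of 18265 genes between the kits, 5673 higher and 5697 lower with the small RNA kit, or 49.9% of calls higher. That balance rests on the scaling: 38.9% of 11719 calls were higher with upper-quartile factors and 16.6% of 14364 with total counts. The median of all genes was −0.06 with TMM, −0.31 with upper-quartile factors and −1.13 with total counts, and changes are to be read relative to it. DESeq2's Wald test called 10987 genes. The kit cannot be told apart from any other difference between the 2 pairs of replicates. For the other splits of 2 and 2 replicates, edgeR called 0 genes each, with 13 genes (replicates 1 and 3 against 2 and 4) and 14 genes (1 and 4 against 2 and 3) at an unadjusted p below 0.05, and DESeq2's Wald test called 2 and 3. Each side of these splits held 1 library of each kit, so the kit difference lay in the residual (coefficient of variation 0.546, against 0.215 over more genes with the kit as a factor), and chance alone would give 913 genes at that p. With the kit as a further factor, which left 1 residual degree of freedom, edgeR again called 0 genes each, with 544 and 652 genes at an unadjusted p below 0.05.

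Gene groups moved with the kit to different degrees. Of 9 measured polymerase III RNAs, 8 were higher with the small RNA kit and 1 lower, with a median of 8.90 on the log2 scale, or 7.85 with total counts. Of 12 small RNAs made by polymerase II, 11 were higher and 0 lower, with a median of 5.58, or 4.50 with total counts. All 13 mitochondrially encoded messenger RNAs were lower, with a median of −4.41, or −5.49 with total counts. Replication-dependent histones had 15 of 17 members higher and 1 lower, with a median of 1.98, or 10 higher and 3 lower with 0.91 under total counts. HIST1H2AG was 4.02 ± 0.11 and HIST1H4C 4.50 ± 0.16 higher (edgeR, adjusted p = 7.0e-05 and 0.00011). Ribosomal protein and elongation factor genes had 17 of 20 higher and 2 lower, or 11 and 3 with total counts, with RPS14 at 3.66 ± 0.15 and RPLP1 at −1.78 ± 0.16 (edgeR, adjusted p = 0.00013 and 0.000724). Glycolysis had 14 of 18 higher and 2 lower, but 6 and 6 with total counts, and oxidative phosphorylation had 17 of 20 higher and 1 lower, which turned to 5 and 11 with total counts. MHC class I genes had 8 of 14 higher and 3 lower, which turned to 2 and 6 with total counts. Pro-apoptotic BCL2 genes had 6 of 10 higher and 1 lower, or 5 and 2 with total counts, with BIK at 3.02 ± 0.12, BAX at 2.32 ± 0.10 and BCL2L11 at −1.86 ± 0.08 (edgeR, adjusted p = 0.000134, 0.000136 and 0.000135). These 9 lists were the ones whose members deviated together between libraries more than random lists matched on expression (permutation, adjusted p from 0.00064 to 0.0181). With total counts 3 were called, the polymerase III, polymerase II and mitochondrial lists. The call of oxidative phosphorylation was lost without replicate 1 (adjusted p = 0.0516) or replicate 2 (0.1003), and that of MHC class I without replicate 2 (0.0512). RNA polymerase II subunits, which missed the threshold (adjusted p = 0.0592), passed without replicate 3 (0.0458), and with each replicate left out 7 to 10 lists were called.

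B cell receptor signalling had 2 of 15 members higher with the small RNA kit and 9 lower, and 0 and 14 with total counts. B cell identity had 6 of 20 higher and 10 lower, and 2 and 16 with total counts. Among them CD79B was at 1.66 ± 0.08, MS4A1 at −0.94 ± 0.12 and CD74 at −1.12 ± 0.10 (edgeR, adjusted p = 0.000179, 0.00215 and 0.000834). DNA methylation and Polycomb genes had 4 of 15 higher and 8 lower, and 0 and 13 with total counts, with DNMT1 at −1.89 ± 0.10 (edgeR, adjusted p = 0.000186). Proliferation genes had 8 of 18 higher and 6 lower, which turned to 2 and 11 with total counts, and MKI67 was at −3.37 ± 0.11 (edgeR, adjusted p = 9.0e-05). Among long non-coding RNAs, 6 of 17 were higher and 5 lower, which turned to 3 and 11 with total counts. GAS5 and SNHG1 were 6.07 ± 0.23 and 6.20 ± 0.20 higher, and MALAT1 was at −2.28 ± 0.14 (edgeR, adjusted p = 0.00012, 9.0e-05 and 0.00026). Adjusted over the list alone, the calls became 6 higher and 11 lower for B cell identity, 10 and 6 for proliferation, 18 and 1 for oxidative phosphorylation, 4 and 9 for DNA methylation and Polycomb, and 6 and 6 for long non-coding RNAs. The other lists of this and the preceding paragraph had the same counts adjusted over the list alone.

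**Figure D4:**
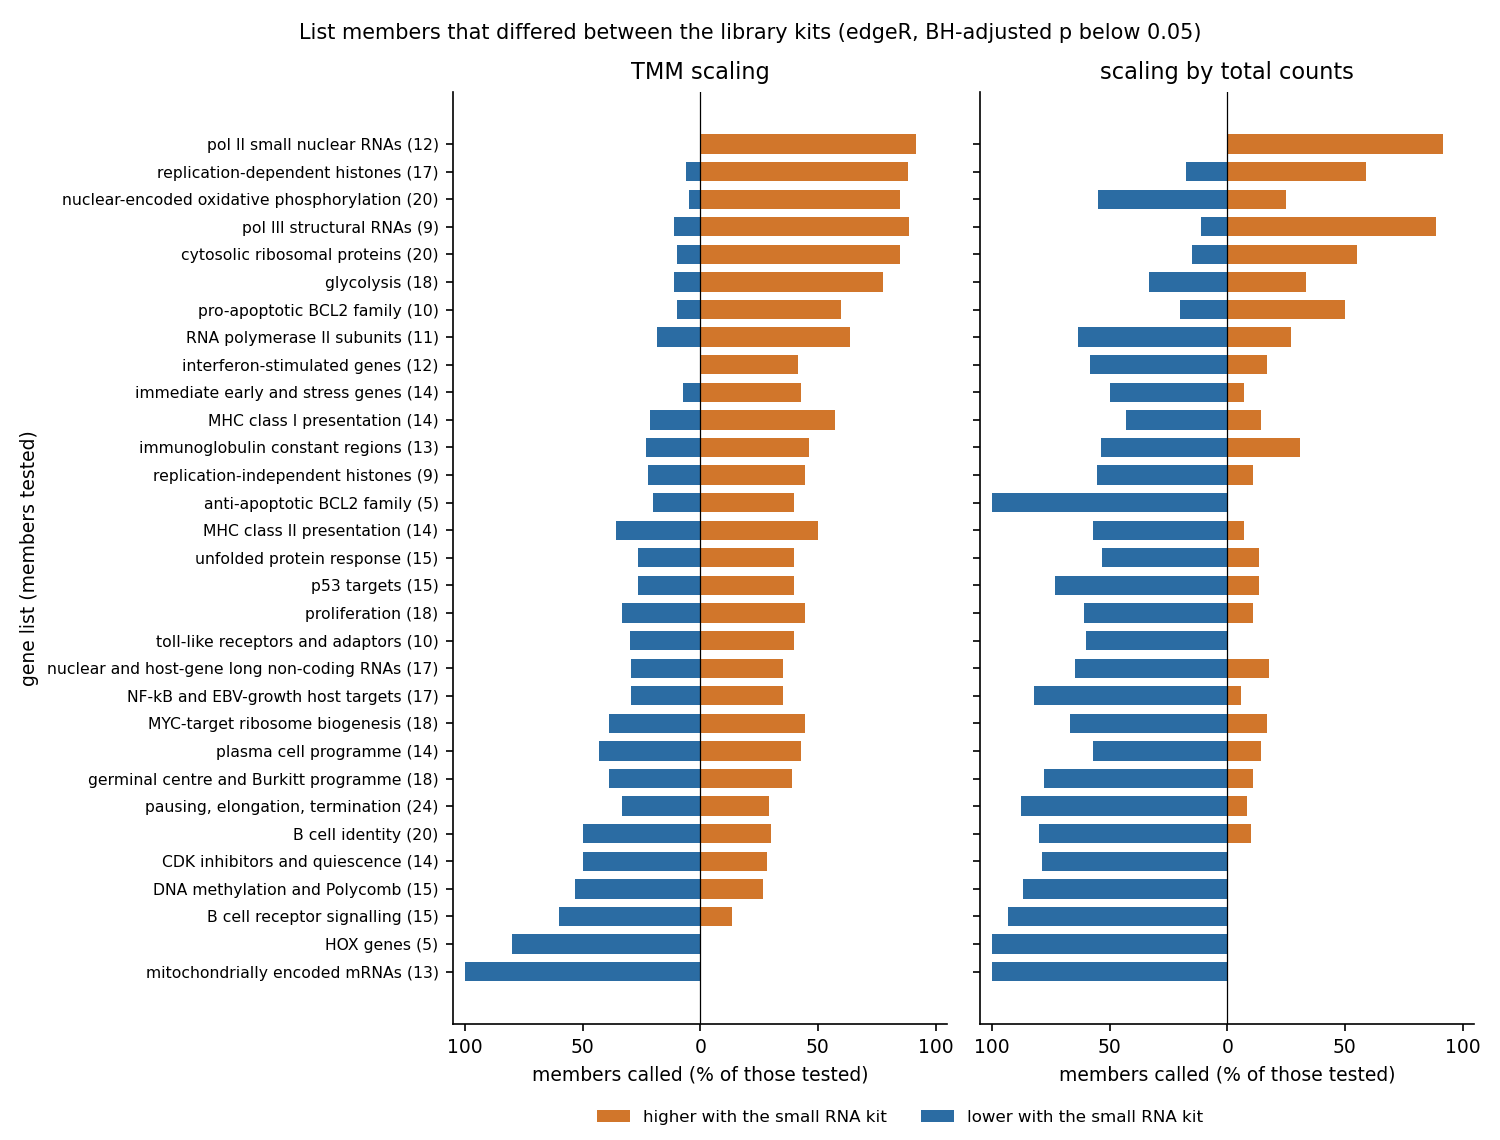
Share of the tested members of each gene list (%) called higher (right) or lower (left) in replicates 3 and 4, made with the small RNA kit, than in replicates 1 and 2, made with ScriptSeq (edgeR). The left panel uses TMM scaling and the right panel total counts, under which oxidative phosphorylation turns from 17 higher and 1 lower to 5 and 11, while polymerase II small RNAs stay at 11 higher and mitochondrially encoded messenger RNAs at 13 lower.

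No library was a copy of another. Per degree of freedom, the chi-square of counts over genes was 86.0 between replicates 1 and 2, 850.3 between replicates 3 and 4, and 2374 to 2864 across kits. Across 10309 protein-coding genes, which are not independent replicates, Pearson's r of log2 levels was 0.990 in each kit and 0.876 to 0.888 across kits, and the SD of the log2 difference was 0.326 and 0.332 within kits against 1.08 to 1.13 across them. The biological coefficient of variation (edgeR) over all 4 libraries was 0.546, and 0.215 with the kit as a factor, 0.202 in replicates 1 and 2 alone and 0.194 in replicates 3 and 4 alone. The filter kept different genes for each, 13768, 18265, 16555 and 15566 in that order. More genes varied beyond counting error than not, 14445 of 15581 (92.7%) over all libraries, against 7087 (45.9%) in replicates 1 and 2 and 3753 (25.6%) in replicates 3 and 4. Among genes that the filter kept, which needed counts in all 4 libraries, the 10 most dispersed were SNORD3C, 3 copies of U2 listed as RF00004, RNU5A-1, RNU5B-1, MT-TE, MT-TS2, AC051619.8 and RN7SL49P. Genes at 0 in 1 kit, RMRP among them, were not ranked. The copies of U2 differed within a kit too, 1 with 53966 and 2537736 counts in replicates 3 and 4 and another with 1227949 and 30593.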

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

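Of the tests in this part, only those for reads shared between near-identical copies and for other cells or a mislabelled sample were written down before their results were seen; the others were chosen after.

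Of 114 values tested for a library far from the other 3, 2 passed Dixon's 95% critical value. Chance alone passes about 1 in 20 only where all 4 libraries are alike. Values that part by kit have a wider range, so that rate does not hold here and an odd library can be missed. The list level of T and NK cell markers was −2.99 in replicate 2 and −3.32 in the others, a gap of 1 as a share of the range. The list level of HOX genes was −2.81 in replicate 2 and −3.32 in the others, again a gap of 1. Both lie near the floor, where the median rests on genes with few counts.

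The difference between replicates 1 and 2 and replicates 3 and 4 is weighed first. Genes with at most 200 bases of exon had a median log2 fold 5.25 above that of longer genes. Of 856 such genes, 597 were higher and 133 lower with the small RNA kit. A small RNA kit keeps short RNAs. Classes of short RNA had already been seen higher there, however, so this comparison adds no separate support for the library kit. Across 9761 protein-coding genes the fold also fell with exon length (Spearman −0.42), but with offsets for exon length, GC and exon number 64.8% of protein-coding genes were still called, against 68.3% before, so these trends are not the whole cause. Both shares come from protein-coding genes tested and normalised among themselves. Other cells or a mislabelled sample stay open. The leading heavy V gene took as little as 30.3% of heavy V counts, under the 50% set beforehand for a single clone. The prediction written beforehand counted a share under 50% in a replicate for this explanation. However, the share was under 50% in every library of both kits, and IGHV3-21 and IGHV1-69D were the 2 leaders in all 4. It does not separate the kits and was read as undecided, which departs from that prediction. No biological explanation was tested, since the design has 1 group.

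Single copies of multi-copy RNAs differed between the replicates of 1 kit. In replicates 1 and 2, RNU1-1 had 107242 and 239 counts and RN7SL5P 1502 and 408073. If reads shared between near-identical copies were the cause, the sum of a family would stay level while its members trade counts; in 8 of 19 combinations of family and kit the sum differed by under 0.5 times as much as the median member, and in 6 of 19 by at least as much. The median over members cannot show a trade between 2 of them, so these counts do not decide. U1 in replicates 1 and 2 was among the 6, at 0.468 for the sum and 0.309 for the median member (log2). There RNVU1-7 had 2795 and 118161 counts, opposite to RNU1-1. HSPA1 in replicates 1 and 2 was also among the 6, at only 0.116 and 0.101. The U2 sums were level, at 79260 and 79503 CPM in replicates 3 and 4. The 7SL sums differed by 1.45 and 1.02 on the log2 scale. Shared reads may account for some families and remain open for others.

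Of 600 list members, 89 had a count of 0 in every library, and 8 of these have no exon base free of another gene on the same strand: RN7SK, RN7SL1, RPPH1, SCARNA2, RNU12, SNORD118, IGLC1 and HIST1H3D. Over all protein-coding genes without such a base, 97.9% (228 of 233) were at 0, against 31.9% of 11013 genes free of neighbours, which is consistent with reads being dropped where exons of 2 genes overlap on the same strand. Another 52 genes had at least 75% of exon bases covered on the opposite strand and at least 90% free on their own strand. Of these, 30.8% were at 0. Their uncovered bases could still collect counts, so this share cannot show whether opposite-strand overlap lost reads. For these 8 genes a 0 may therefore say nothing about expression.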

How the results depend on the processing

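The within-kit values, division by exon length, the kit factor, the protein-coding subset and the offsets were tests chosen only after the results were seen. The alternative of no division by length coincides with the values reported. No paired analysis was possible because there is 1 group. The coefficient of variation, 0.546, was 0.770 without a filter, 0.675 at a mean count of at least 50, 0.539 to 0.571 with each replicate left out, and 0.215, 0.202 and 0.194 with the kit as a factor and in each kit alone. Each of these settings kept its own set of genes. Genes varying beyond counting error numbered 7087 and 3753 in each kit alone, where fewer libraries were tested and no kit difference entered. With each replicate left out, which kept both kits, they numbered 13529 to 14267. Between kits, 7421 of 10862 protein-coding genes were called when these genes were tested and normalised among themselves, and 7038 with offsets. DESeq2's Wald test called 2 and 3 genes in the other splits, where edgeR called 0 both without and with the kit as a factor. Called list levels, 21 in all, numbered 13 against expressed genes alone, 31 by the mean of the members' levels, 24 per kb, 19 and 18 in each kit alone and 18 to 21 with each replicate left out. Called list spreads, 9 in all, numbered 7 to 10 with each replicate left out, 3 with total counts and 3 and 4 in each kit alone; the cause was not tested. Replication-dependent over replication-independent histones came to 4.45 per kb and 3.85 in replicates 3 and 4 alone, both past the threshold. Mitochondrially encoded over nuclear-encoded genes came to 3.20 per kb, 0.067 to 1.91 with each replicate left out (1.91 without replicate 3 and 1.72 without replicate 4 passed), 3.55 in replicates 1 and 2 alone and −1.65, with the sign turned, in replicates 3 and 4 alone. BCL2 over BCL2L1 reversed to −1.23 per kb, as division by unequal exon lengths must shift it. Without mitochondrial, ribosomal, 7SK, 7SL and small nuclear RNA genes in the total, protein-coding genes held 72.2%, processed pseudogenes 7.59% and long non-coding RNAs 2.17%. Otherwise 336 list levels were unchanged in call, 16 gained and 20 lost it; among gene pairs 180 kept their value, 27 moved and 1 reversed; among folds of named genes 308 kept their call, 1 gained it (HLA-C, 1.22 without replicate 2) and 5 lost it (PSMB9 with total counts, and RNU6-74P and RNU6-936P without replicate 3 or 4). The number of expressed genes ranged from 11023 to 14124.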

Other observations

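The tests of this part were all chosen only after the results were seen, except that of the heavy V genes.

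Immunoglobulin V genes gave few counts. The leading heavy V gene was IGHV3-21 in replicates 1, 3 and 4, with 40.1%, 37.3% and 42.1% of heavy V counts, and IGHV1-69D in replicate 2, with 30.3%. IGKV3D-20 led the kappa V genes in every library with 47.6% to 51.1%, and IGLV6-57 the lambda V genes with 56.5% to 80.9%, on totals of 196 to 214 lambda V counts.

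Several processed pseudogenes had a higher mean CPM than their named parent gene. Of 72 with a mean of at least 100 CPM and a named parent, 27 lay above it. BWA does not split reads across introns. If it aligned the reads, which is not stated, junction reads of the parent can be placed on the pseudogene. Multi-mapping settings are not given either. The ratios therefore do not show that these pseudogenes were transcribed above their parents. RPL7P9 averaged 1549.5 CPM against 34.5 CPM for RPL7, 44.9 times as much, RPL9P9 843 CPM against 76.2 CPM for RPL9, and EEF1A1P5 10487 CPM against 7641 CPM for EEF1A1.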
